A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

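Gene expression was measured in rice (Oryza sativa Japonica group, cultivar Katy) on an Affymetrix rice genome array, an oligonucleotide array on which each transcript is read by a probe set. The 9 arrays cover 3 stages with 3 biological replicates each: unfertilized egg cells, fertilized egg cells at about 1 hour after pollination (hap; 1 to 1.5 hap in the series text), and zygotes at about 3 hap (2.5 to 3 hap). Per the labels' protocols, about 100 cells isolated without enzymes went into each sample, at about 25 pg of RNA per cell and 2.5 ng in total, and the RNA went through 2 cycles of cDNA synthesis and amplification before biotin labelling. A free-text field of the labels names seedlings for the egg arrays, pollen for the fertilized egg arrays and sperm cells for the zygote arrays; were it right, every comparison would mean something else. The groups follow the titles, characteristics and series text, which all name egg cells, fertilized egg cells and zygotes.

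The deposited table holds 1 linear signal intensity per probe set and array, which the authors made with MAS5, per the submitters' processing notes; the MAS5 version is not given in the sources used here. The mean of each array after trimming 2 percent from either end was 500.1, so the deposited intensity values were scaled to a common trimmed mean. The file has 57381 probe sets, of which 123 Affymetrix control and 64 reporter probe sets were left out of the tests, leaving 57194; the reporters were left out as controls only after first fits had been seen. An annotation table of the array gave exactly 1 gene for 22436 probe sets, several genes for 95 and none for 34663. Symbols and synonyms came from the RefSeq gene table of assembly ASM3414082v1 (GCF_034140825.1), which held all 17905 genes of the array, 2427 of them with an informative name. Coordinates are not used here.

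From these values, log2(signal + 15) was computed, the offset being the 25th percentile of all values, and probe sets with a mean at or above the median of all probe sets were kept. The 28597 probe sets kept cover 15342 genes. Fold changes are on the log2(signal + offset) scale and understate changes of dim probe sets. No further normalization was applied. Linear models were fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend) on all 9 arrays, with a moderated F test over the stages and 3 pairwise contrasts, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Text processing and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision of every value.

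Gene lists were tested with camera at an inter-gene correlation of 0.01, with the brightest probe set of each gene and at least 5 kept genes per list, which left 24 lists. The lists had been fixed before the data were examined as word patterns on gene descriptions. The tables used here pair genes with symbols only, so equivalent symbol patterns were written after the annotation was read and before any list or gene test was examined. The core histone list (2 genes), the ribosome biogenesis list (4 genes) and the egg apparatus list (0 genes) were too short to test. Genes are named by a rule fixed before the data were examined: in each contrast, the 12 largest rises and 12 largest falls among probe sets past the threshold whose 3 arrays of one stage all lie above the 3 of the other and that pair with exactly 1 gene with an informative description, here read as an informative symbol; where no probe set passed, the 5 smallest unadjusted p-values in each direction; for marker lists, also the 3 brightest members. The same rule was applied to a fit with array quality weights, which lets noisier arrays count less. That fit had been fixed before the data were examined as a variation of the analysis, while naming genes from it was decided after both fits were seen. Its values are named as such wherever they stand. Unless named with weights, the single ribosomal and heat shock genes given below fall outside this rule and were picked from the same data as examples.

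Control measures were compared between stages by exact permutation over the 280 partitions of the arrays into 3 groups of 3. The smallest two-sided exact p for 3 arrays against 3 is 0.1. The tests were checked on simulated data with 28597 probe sets and the spread of each probe set and array seen here. Noise was drawn independently for each probe set, so shifts shared by many probe sets of an array were left out. The counts of false calls below do not cover such shifts. For fertilized egg minus egg, the main test recovered 2 percent of 2-fold, 18 percent of 4-fold, 54 percent of 8-fold and 64 percent of 16-fold changes with 0 false calls. With array weights these shares were 26, 50, 82 and 98 percent with 8 false calls. The simulated spread of each array was set from the array weights of these data, so this gain was built in. With equal spread in all arrays, the shares were 2, 18, 46 and 58 percent with and without weights, with 0 false calls. For zygote minus egg, camera recovered the 1 shifted list and called 0 of 20 unchanged lists. The alternatives changed the offset, the filter, the scaling, the variance model, the arrays in the fit, the fold threshold and the set test, added the replicate number or an RNA quality ratio to the model, and left out each array in turn.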

Results

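The data are 9 arrays of rice egg cells, fertilized egg cells and zygotes, 3 biological replicates per stage, and the design asks how transcript levels differ before and soon after the gametes and their nuclei fuse. The median signal of the rice probe sets lay between 36.5 and 50.9 in egg cells, between 47.3 and 95.4 in fertilized eggs and between 54 and 218 in zygotes. The arrays were scaled to a common trimmed mean, so these medians do not measure a stage difference in expression. Replicates of egg cells resembled each other most, with a mean correlation across probe sets of 0.936 to 0.956 within the group, against 0.884 to 0.916 in fertilized eggs and 0.688 to 0.778 in zygotes. Zygote replicate 2 had a median correlation of 0.684 with the other arrays, and the other 8 had 0.843 to 0.916. Zygote replicate 1 correlated at 0.903, 0.901 and 0.917 with the egg arrays, but at 0.667 and 0.847 with zygote replicates 2 and 3. Zygote replicate 3 correlated at 0.855 to 0.861 with the egg arrays and at 0.847 and 0.709 with zygote replicates 1 and 2. Probe sets of 1 array are not independent replicates.

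Photosynthetic, anther and storage tissue markers were described in every array because a label field names seedlings for the egg arrays, pollen for the fertilized egg arrays and sperm cells for the zygote arrays. CAB2R, a chlorophyll a/b-binding protein of leaves, had a signal of 14210 ± 3680 in egg cells, 11770 ± 1880 in fertilized eggs and 7127 ± 5150 in zygotes (SD, n = 3). PETE, which encodes plastocyanin, had 2896 ± 1030, 3739 ± 1220 and 2183 ± 1240, and CHL1 had 1047 ± 270, 702.7 ± 108 and 834.6 ± 625 (SD, n = 3). Among 12 genes of anther and pollen development, MTR1 had 3123 ± 454, 6451 ± 807 and 3024 ± 830, and MSP1 had 1141 ± 487, 1139 ± 240 and 1040 ± 81.9 (SD, n = 3), while INP1 had 108.7 ± 23.7, 113.3 ± 28.6 and 179 ± 134. The list holds genes of the anther wall and pollen coat and no sperm cell gene. The endosperm list was led by GBSS-I, a starch synthase, at 10280 ± 4060, 21410 ± 12700 and 15920 ± 6840, followed by SS1 and Q-enzyme at 2591 ± 607 and 1339 ± 196 in egg cells (SD, n = 3). The ovule wall and nucellus list was led by the aquaporin AQP, the lipid transfer protein LTPL1 and the MADS-box gene MADS58, at 16650 ± 5260, 14110 ± 3910 and 8081 ± 1560 in egg cells (SD, n = 3). The median signal of the 18 photosynthetic genes was 225.1 to 400.8 over the 9 arrays, and that of the 12 anther and pollen genes was 15.74 to 66.41. That of the 33 ovule wall genes was 715 in egg cell replicate 2, 209.9 and 273.6 in the other egg arrays and 255.7 to 466.6 in the later arrays. None of the 4 marker lists passed the threshold in any contrast by limma's camera test. For fertilized egg minus egg, adjusted p was 0.875, 0.353, 0.627 and 0.353 in the order photosynthetic, anther and pollen, endosperm, ovule wall. The test used the kept genes only, 16, 5, 9 and 27 in the same order. Without egg cell replicate 1 the ovule wall list passed, lower than in egg cells, at about 1 hap (adjusted p = 0.0462 by limma's camera) and about 3 hap (adjusted p = 0.0178).

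RNA controls separated the egg arrays from the rest. The poly-A spike transcripts, added before amplification, relative to the hybridization spike, added after it, gave a ratio of 0.0398 to 0.0763 in egg arrays, 0.337 to 0.51 in fertilized egg arrays and 0.368 to 0.657 in zygote arrays. On the log2 scale the means were -4.22 ± 0.47, -1.26 ± 0.30 and -1.11 ± 0.45 (SD, n = 3; exact permutation p = 0.025 over the 3 stages, adjusted p = 0.118 over 11 control measures). The hybridization spike itself read 26770 to 39310 in egg arrays and 43300 to 184700 in fertilized egg arrays. In zygote arrays it read 85940 to 891900 (exact permutation p = 0.0393 over the 3 stages). It was highest in zygote replicate 2, which also had the highest median signal of rice probe sets. The 18S rRNA signal was 14670 to 24660 in egg arrays and 1886 to 8275 in the later 6 (exact permutation p = 0.0429, n = 3 per stage). The log2 ratio of 3′ to 5′ signal over actin, cyclophilin and GAPDH was 6.18 ± 0.25, 7.20 ± 1.25 and 7.03 ± 1.11 (SD, n = 3), with an exact permutation p of 0.421. None of the 11 measures passed the threshold after adjustment.

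**Figure D1:**
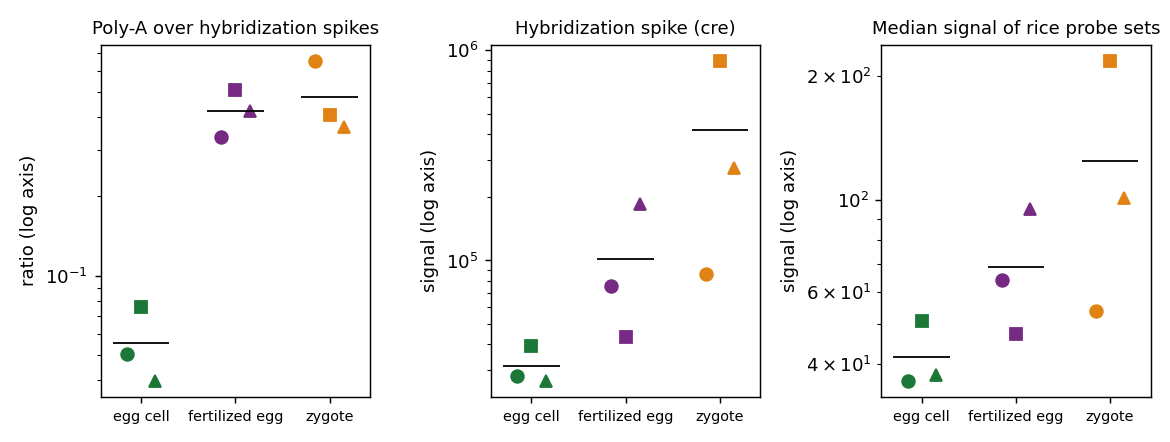
Control measures per array, on log axes: the ratio of poly-A to hybridization spikes, the hybridization spike signal and the median signal of rice probe sets. Circles, squares and triangles are replicates 1, 2 and 3 of each stage and bars are means; the ratio lies between 0.0398 and 0.0763 in egg arrays and at or above 0.337 in the others.

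Over the 3 stages, the probe sets that differed were mostly those bright in egg cells. The moderated F test of limma called 18 of 28597 probe sets, 17 of them highest in egg cells and 1 lowest, and 6 of the 18 pair with exactly 1 gene. At an unadjusted p under 0.05 there were 3887. RAB21, a dehydrin induced by abscisic acid and drying, was among them with an adjusted p of 0.0221 by limma, and Rf2, a fertility restorer gene, with 0.032. The ratio of poly-A to hybridization spikes also parted egg arrays from the rest, and with it in the model the count was 0. The count was 0 without egg cell replicate 1 or 3, 2 without egg cell replicate 2, 7, 1 and 8 without fertilized egg replicates 1, 2 and 3, 121 without zygote replicate 1 and 32 without zygote replicate 2.

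The comparison of fertilized egg cells with egg cells addresses the time around gamete fusion. In the fit of all arrays, 12 probe sets passed the threshold by limma, 11 lower and 1 higher in fertilized eggs, with folds from 4.39 to 21.8. Among the called probe sets 3 pair with 1 gene and none of these has an informative name, so the rule names none. The only one higher, LOC4332413, was singled out after its values were seen: it had 2598 ± 656 in egg cells and 16850 ± 6190 in fertilized eggs (SD, n = 3; log2 change 2.66 ± 0.34, SE; adjusted p = 0.0199 by limma). LOC4331855, also chosen after its values were seen, had 2864 ± 439 and 635.5 ± 97.1 (SD, n = 3), and stood at 2233 ± 221 in zygotes. At an unadjusted p under 0.05 there were 2544 probe sets. The count was 1 without egg cell replicate 3 or fertilized egg replicate 1, 2 without egg cell replicate 1 or fertilized egg replicate 2, 4 without fertilized egg replicate 3, 45 without zygote replicate 1 (20 higher, 25 lower) and 67 without zygote replicate 2 (12 higher, 55 lower). Without egg cell replicate 2 it was 18, of which 11 were higher and 7 lower. With the spike ratio in the model, or without a trend in the variance model, it was 0. In a fit of only the 6 arrays compared it was 155, 47 higher and 108 lower.

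With array quality weights the same comparison called 569 probe sets higher and 678 lower, and the 12 called without weights were all among them. The 12 largest rises among named genes included chitinases and genes of phytoalexin synthesis. The chitinases Cht4 and chia4a, which cleave fungal cell walls, had log2 changes of 6.66 ± 0.82 and 5.29 ± 0.67 (SE; adjusted p = 0.000652 and 0.000769 by limma with weights), Cht2 and CH16 had 3.54 ± 0.57 and 3.09 ± 0.60, and the pathogenesis-related gene PBZ1 had 4.30 ± 0.47. Genes of diterpenoid phytoalexin synthesis, which makes antimicrobial compounds of rice, were CYP71Z7 at 3.29 ± 0.60, CPS2 at 2.96 ± 0.48, CYP701A8 at 2.80 ± 0.45 and OsMAS at 2.70 ± 0.51 (SE). JAZ7, a repressor of jasmonate signalling, had 4605 ± 3580 in egg cells and 23080 ± 1230 in fertilized eggs (SD, n = 3). In the unweighted model with the spike ratio, the estimate for JAZ7 turned to a fall without passing the threshold. The heat stress factor HSF11 and the phenylpropanoid gene 4CL5 had 2.54 ± 0.56 and 2.41 ± 0.40 (SE). Without weights none of these 12 passed the threshold: Cht4 had a log2 change of 6.73 ± 1.58 (SE; adjusted p = 0.245 by limma) and PBZ1 4.73 ± 0.92 (adjusted p = 0.134). The arrays with the highest log2 ratio of 3′ to 5′ signal, fertilized egg replicate 3 (8.62) and zygote replicate 2 (8.15), read 13140 and 8245 for PBZ1, and the array with the lowest, zygote replicate 1 (5.93), read 310.8. Fertilized egg replicate 1 (6.32) and egg cell replicate 2 (6.46) were alike in the ratio and read 3100 and 134.9. PBZ1 and these arrays are examples picked from the same data and do not decide whether RNA quality shaped the rises. Of the 10 other chitinase genes, 5 were above 0 and 5 below without passing, from CH6 at 1.22 ± 0.81 to Chia1d at -4.93 ± 1.38 (SE; adjusted p = 0.36, and 0.0534 with weights), which read 10060 in egg cell replicate 2 and 284.4 and 104.7 in the other egg arrays. A list of chitinase and defence genes written after these values were seen did not pass in its other 21 members (p = 0.722 by limma's camera, n = 21 genes; 0.251 with weights).

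The largest falls with weights were RAB21 at -3.19 ± 0.35, the glutaredoxin gene GRXC3 at -3.02 ± 0.53, Rf2 at -2.43 ± 0.24 and OsSGS3, of the small RNA pathway, at -2.38 ± 0.37 (log2, SE; adjusted p from 0.000134 to 0.00749 by limma with weights). They were followed by eIF-4G at -2.30 ± 0.51, ADC1, an arginine decarboxylase of polyamine synthesis, at -2.27 ± 0.35, OsWNK9 at -2.02 ± 0.39, MYBS1 at -1.98 ± 0.48 and LIR1 at -1.98 ± 0.45. OsCASPL5B2, SAT1 and the jasmonate receptor gene COI1B had -1.96 ± 0.39, -1.89 ± 0.34 and -1.86 ± 0.33. In the unweighted model with the spike ratio, the estimate for GRXC3 turned to a rise without passing the threshold. Of the 24 genes named with weights, 9 have other probe sets, and in 5 of these a brighter one did not pass in the same direction: OsSGS3 at 0.18 ± 0.18, ADC1 at 0.22 ± 0.19, eIF-4G at -0.15 ± 0.24, SAT1 at -0.23 ± 0.23 and OsCASPL5B2 at -1.10 ± 0.36 (SE). Another split of the same 6 arrays called 1460 with weights, more than the stages did.

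**Figure D2:**
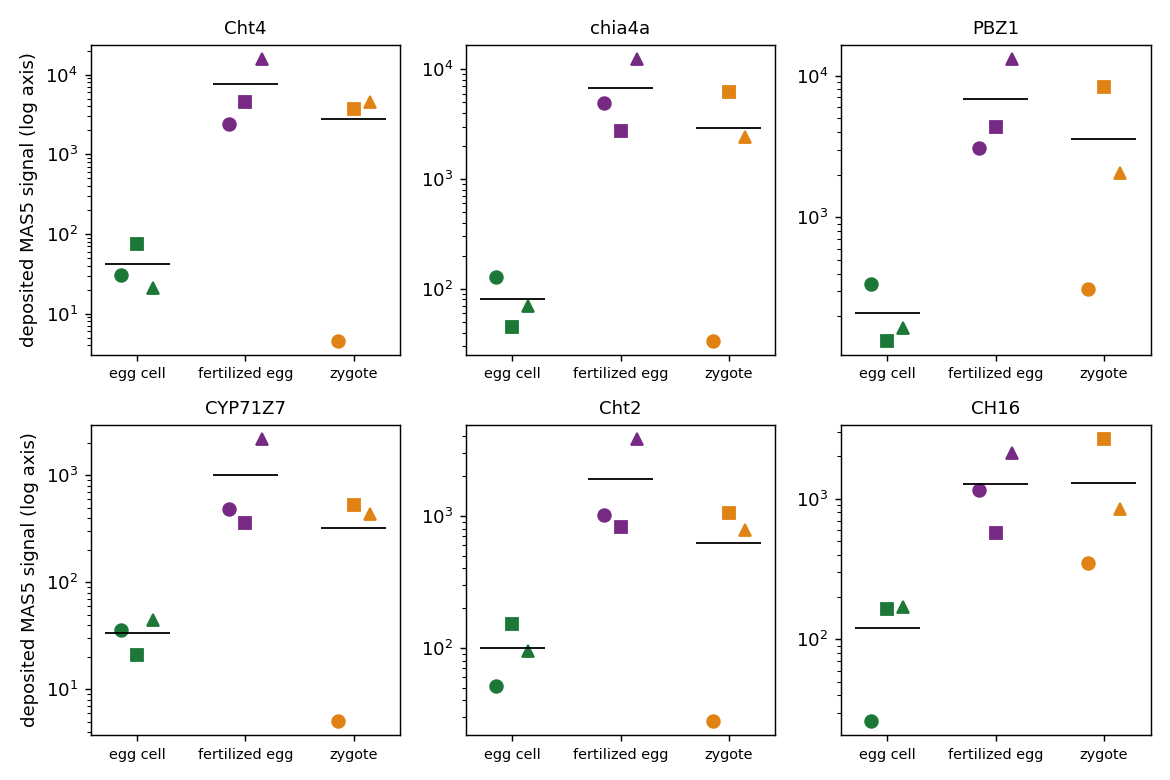
Deposited MAS5 signal per array, on log axes, of Cht4, chia4a, PBZ1, CYP71Z7, Cht2 and CH16, picked for their rises with weights; circles, squares and triangles are replicates 1, 2 and 3 and bars are means. All 3 fertilized egg arrays lie above all 3 egg arrays, which the naming rule required. Zygote replicate 1 reads 4.616 for Cht4 against 3711 and 4529 in the other zygote arrays.

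Among gene groups, cytosolic ribosomal proteins and heat shock proteins were shifted up in fertilized eggs. The 23 ribosomal protein genes had a median log2 change of 0.61 against 0.01 for all genes, 21 of them above 0 (adjusted p = 1.67e-06 by limma's camera; adjusted p = 0.515 with an estimated correlation). None of them passed the threshold over all probe sets, and 1 did when adjusted over the list alone. As examples picked from these data, RPL7A-2 had 5921 ± 992 in egg cells and 13420 ± 2840 in fertilized eggs, and RPL10A had 13970 ± 1290 and 25040 ± 3890 (SD, n = 3). The 31 heat shock and chaperone genes had a median of 0.47 with 22 above 0 (adjusted p = 0.00978 by camera; adjusted p = 0.515 with an estimated correlation), none passing over all probe sets and 0 when adjusted over the list alone. HSP81-1, HSP81-2 and HSP81-3, which encode HSP90 chaperones, had signals of 14740 ± 785, 32210 ± 415 and 34130 ± 6050 in egg cells and 30930 ± 15600, 57710 ± 22800 and 85790 ± 40700 in fertilized eggs (SD, n = 3), but another HSP81-3 probe set went from 11570 ± 2430 to 6619 ± 5250. Neither list passed after quantile normalization (adjusted p = 0.0854 and 0.0823 by camera). Lists of genes as bright as the ribosomal ones had a median of 0.41.

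The other 22 lists did not pass in this comparison, with adjusted p from 0.108 to 0.905 by camera. Without egg cell replicate 1, DNA replication and translation factors passed upward and auxin signalling downward (adjusted p = 0.0462 each), without egg cell replicate 2 vesicle traffic passed downward (0.0374), and without fertilized egg replicate 3 DNA replication passed upward (0.0482). Translation factors, glycolysis and vesicle traffic had adjusted p = 0.108 each with median log2 changes of 0.29, 0.52 and -0.34. Auxin signalling had -0.27 (adjusted p = 0.144) and DNA replication 0.32 (0.19). Calcium signalling, redox enzymes, the proteasome, mitochondrial respiration, RNA splicing and F-box proteins had 0.22, 0.14, 0.10, 0.11, 0.14 and -0.16, all with adjusted p = 0.353. Cyclins, DNA methylation and small RNA pathways, histone modifiers, cytokinin and ethylene pathways, embryo regulators, cell wall genes and the cytoskeleton had medians between -0.06 and 0.15, with adjusted p from 0.753 to 0.905.

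The comparison of zygotes with fertilized eggs addresses the time around nuclear fusion, and no probe set passed the threshold in it by limma. At an unadjusted p under 0.05 there were 3018, and with array quality weights the count was also 0. The smallest p-values among named genes, none past the threshold, were for IAA10, an auxin response repressor, at 267.1 ± 22.6 in fertilized eggs and 1856 ± 946 in zygotes (SD, n = 3; adjusted p = 0.211 by limma), and for OsPP2C45, osysl12, CCR1 and ADC1, with log2 changes of 4.47 ± 0.82, 2.90 ± 0.62, 2.57 ± 0.60 and 1.73 ± 0.42 (SE). Brighter probe sets of OsPP2C45 and ADC1 stood at 0.01 ± 0.46 and 0.00 ± 0.28. In the other direction PLA2-III, a phospholipase gene, had 12210 ± 3470 and 2630 ± 930 (SD, n = 3; adjusted p = 0.152), and OsWNK4, OsbZIP37, JAZ3 and ILL2 had log2 changes of -1.54 ± 0.27, -3.59 ± 0.67, -1.70 ± 0.35 and -3.91 ± 0.80 (SE). No list passed, with adjusted p from 0.0725 for redox enzymes (median -0.33, 41 of 55 genes below 0) to 0.836 by camera. Redox enzymes passed without zygote replicate 1 (adjusted p = 0.0295) and without fertilized egg replicate 1 (0.0381), and had 0.608 without zygote replicate 2. Without zygote replicate 1 the count was 6, and without zygote replicate 3 it was 3.

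Zygotes differed from egg cells in 20 probe sets by limma, all lower in zygotes, with folds from 4.19 to 56.3. RAB21 had 7420 ± 2080 in egg cells, 765.2 ± 43.7 in fertilized eggs and 164.2 ± 161 in zygotes (SD, n = 3; log2 change -5.81 ± 0.60, SE; adjusted p = 0.00844 by limma). Rf2 had 7396 ± 156, 1621 ± 489 and 1398 ± 499 (SD, n = 3; log2 change -2.46 ± 0.35; adjusted p = 0.0346), and OsPDIL2-3, a protein disulfide isomerase-like gene, had 3634 ± 653, 2410 ± 665 and 865.8 ± 223 (SD, n = 3; log2 change -2.07 ± 0.33; adjusted p = 0.0484). At an unadjusted p under 0.05 there were 4584 probe sets. The count was 0 without any single egg array, 10 without fertilized egg replicate 1 or 3, 13 without fertilized egg replicate 2 and 830 without zygote replicate 1, of which 391 were higher and 439 lower, so the single direction is lost without that array. With the spike ratio in the model it was 0, RAB21 then standing at -5.71 ± 2.42 and Rf2 at -0.12 ± 1.25 (SE).

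**Figure D3:**
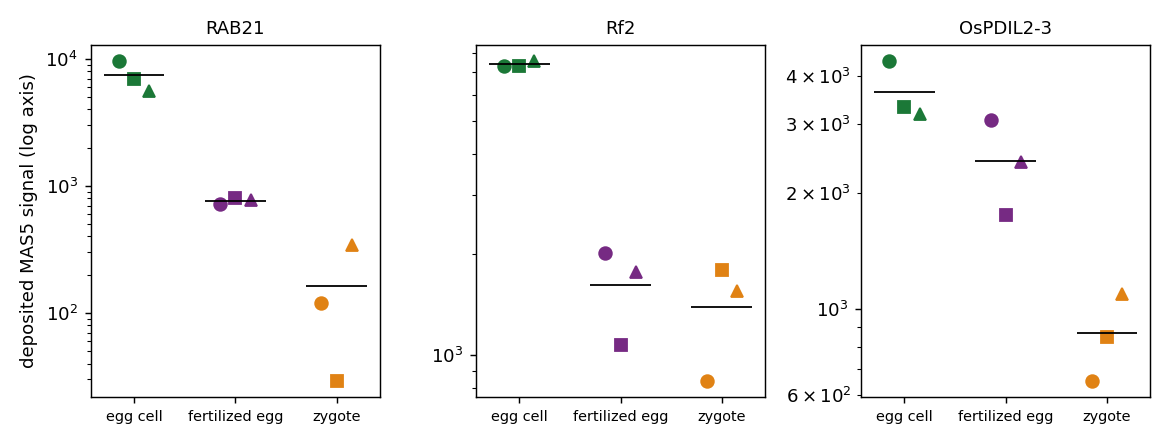
Deposited MAS5 signal per array, on log axes, of the 3 named genes that passed the threshold between zygotes and egg cells; circles, squares and triangles are replicates 1, 2 and 3 and bars are means. All 3 zygote arrays lie below all 3 egg arrays, which the naming rule required. RAB21 has a mean of 7420 in egg cells and 164.2 in zygotes.

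With array quality weights, 230 probe sets were higher and 331 lower in zygotes than in egg cells. The rises included the transcription factor OsWRKY76 at 3.92 ± 0.61, OsMAS at 3.20 ± 0.70, CPS2 at 2.89 ± 0.66, CML27 at 2.30 ± 0.54 and HPT1 at 2.15 ± 0.49 (log2, SE). They also included the translation factor GOS2 at 1.94 ± 0.36, the ribosomal protein RPS21 at 1.92 ± 0.37, Osr40c1 at 1.76 ± 0.33, the glycolytic aldolase FBA1 at 1.75 ± 0.34, the tubulin TID1 at 1.68 ± 0.31 and TCTP at 1.63 ± 0.32. The falls were led by RAB21 at -5.04 ± 0.48, OsbZIP37 at -3.97 ± 0.55, the dehydrin RAB16B at -3.63 ± 0.77, OsPP2C10 at -3.21 ± 0.59, LIR1 at -2.92 ± 0.62 and the mitochondrial gene cob at -2.59 ± 0.60. PDC, Rf2, CDKG-2, OsSGS3 and APG4A had -2.57 ± 0.63, -2.45 ± 0.33, -2.31 ± 0.54, -2.31 ± 0.51 and -2.31 ± 0.46. Of the 23 genes named here, 11 have other probe sets, and in 8 of these at least 1 points the other way. HSP81-3 has 1 at 2.03 ± 0.37 and another at -2.40 ± 0.52. The brighter probe set of PDC was at 1.33 ± 0.36 (adjusted p = 0.0664), those of OsSGS3 and HPT1 at 0.06 ± 0.24 and -1.12 ± 0.33, and dimmer ones of GOS2 and RPS21 at -1.22 ± 0.37 and -1.02 ± 0.36. Dim probe sets of TCTP and CDKG-2 were at -0.18 ± 0.52 and 0.50 ± 0.62. Brighter ones of CDKG-2 and CML27 were at -0.04 ± 0.34 and 1.10 ± 0.45 and did not pass. Most of these calls are lost without 1 zygote array. Without zygote replicate 1 the weighted fit called 13 probe sets, 5 higher and 8 lower. Without zygote replicate 2 it called 10, all lower. The array weights were 0.427, 0.181 and 1.03 in zygote replicates 1, 2 and 3, and 3.13, 0.946 and 3.49 in the egg replicates. The weighted zygote values thus rest most on zygote replicate 3, and the weighted fit was not run without it.

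The 23 ribosomal protein genes were shifted up in zygotes too, with a median log2 difference from egg cells of 0.47 against -0.08 for all genes and 20 of them above 0 (adjusted p = 6.21e-06 by limma's camera; adjusted p = 0.73 with an estimated correlation). None passed over all probe sets, and 7 did when adjusted over the list alone. The median of lists of equally bright genes was 0.48. With quantile normalization the list had adjusted p = 0.0123 by camera, and with quantile normalization and weights 0.442. RPS21 had 33910 ± 4360 in egg cells and 139300 ± 71100 in zygotes, and RPS27AB had 16400 ± 2300 and 44870 ± 12500 (SD, n = 3). The other 23 lists had adjusted p from 0.0749, for glycolysis, to 0.996 by camera. Glycolysis passed upward without fertilized egg replicate 3 (adjusted p = 0.034), zygote replicate 2 (0.0353) or zygote replicate 3 (0.0289), and DNA replication without egg cell replicate 1 (0.0178) or zygote replicate 3 (0.0289). Heat shock genes had a median of 0.15 (adjusted p = 0.22).

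Between both comparisons against egg cells, 3 probe sets were called in the same direction, all lower after fertilization. Independent lists would share 0.00769, and 50 simulations of unchanged groups against the same egg arrays shared at most 0. The log2 changes of both comparisons correlated at 0.509 across probe sets, against 0.23 in the simulations, with a covariance of 0.370 against 0.0849. The simulated arrays held independent noise and no shift shared by the later arrays. A difference in amplification between egg and later arrays, which the spike ratio leaves open, is therefore not covered by them. Both comparisons use the same 3 egg arrays, which are too few to split. The shared count was 0 without any single egg array, 1 without any single fertilized egg array, 32 without zygote replicate 1, 10 without zygote replicate 2 and 1 without zygote replicate 3.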

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

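The fits with weights after leaving out a zygote array, with quantile normalization and weights, and with the spike ratio as a covariate were chosen after seeing the data. No cause of the changes below was tested. The probe sets differing among the 3 stages, 18 in the fit reported, numbered 29 with the larger offset, 30 without a filter, 5 after quantile normalization, 7 after 75th-percentile scaling, 0 without a trend, 1569 with weights (844 without zygote array 1, 366 without zygote array 2), 977 with quantile normalization and weights and 0 with the spike ratio. Leaving out 1 array gave 0 to 121.

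For fertilized egg minus egg (12), the counts were 7 with quantile normalization, 2 with 75th-percentile scaling, 0 without a trend, 155 in the 6 arrays compared, 1247 with weights (1307 and 866 without zygote array 1 or 2), 1379 with quantile normalization and weights, and 0 with the spike ratio, and 1 to 67 with 1 array left out. For zygote minus fertilized egg (0), leaving out 1 array gave 0 to 6, and weights without zygote array 1 gave 2. For zygote minus egg (20), the counts were 13 without an offset, 9 with quantile normalization, 0 without a trend, 11 with the 3′ to 5′ ratio as a covariate, 2 in the 6 arrays compared, 561 with weights (13 and 10 without zygote array 1 or 2) and 0 with the spike ratio, and 0 to 830 with 1 array left out. Quantile normalization with weights called 24, 3 higher and 21 lower, against 230 and 331 with weights alone. The shared calls (3) numbered 5 with the larger offset, 1 under either scaling, 0 without a trend, 176 with weights (7 and 8 without zygote array 1 or 2), 17 with quantile normalization and weights and 0 with the spike ratio, and 0 to 32 with 1 array left out. Named genes, counted per comparison with at most 12 in each direction so that a gene can count more than once (3), numbered 5 with the larger offset, 1 with quantile normalization, 0 without a trend, 48 with weights (27 without either zygote array), 28 with quantile normalization and weights and 0 with the spike ratio, and 0 to 35 with 1 array left out.

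With the replicate number as a replicate block, 6 probe sets differed among stages, 8 between zygote and egg, 1 was shared and 1 gene was named. Same-numbered arrays did not deviate together: 1 of 9 pairs correlated over 0.1, the range was -0.22 to 0.14, and 2 of 9 arrays were closest to their own number.

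The 3 list calls numbered 5 among the brightest 25 percent of probe sets, 0 with quantile normalization and weights, 1 with the spike ratio, 0 with an estimated correlation and 0 with fry, and 3 to 9 with 1 array left out, where 14 calls were gained and 0 lost. Ribosomal proteins in fertilized eggs had adjusted p = 0.0854 with quantile normalization, 0.223 with weights added, 0.934 with the spike ratio, 0.515 with an estimated correlation and 0.121 with fry. In zygotes these were 0.0123 with quantile normalization, where the list still passes, 0.442 with weights added, 0.924, 0.73 and 0.284. The fry test asks whether a list changed at all, while camera asks whether it differed from the other genes. Under quantile normalization DNA replication and the proteasome also passed in zygotes, upward, at 0.0123 each. For heat shock proteins and chaperones, fertilized egg minus egg, adjusted p was 0.224 with the polyA over hybridization spike ratio as covariate. The other settings gave 0.0823, 0.0595, 0.515 and 0.121, with 0.104 for the 3′ to 5′ ratio and 0.129 for means of probe sets. Quantile normalization moved the median log2 change of all probe sets between zygote and egg from 0.05 to -0.21. Of the 59 named values, 3 were called and none of these reversed in 72 alternatives, of which 38 lost the call. Of the other values, JAZ7 and GRXC3 reversed with the spike ratio, at -0.53 and 1.11, without passing the threshold. That covariate widened the errors, for RAB21 in zygote minus egg from 0.60 to 2.42 (SE), so these signs are uncertain. Signals near the offset limit every fold of dim probe sets.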

Other observations

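The split counts, the count without zygote replicate 2, the count with the spike ratio and the ovule wall test were chosen after their results were seen. Some small RNA and chromatin genes were bright at every stage. AGO1B had 29440 in egg cells, 33090 in fertilized eggs and 30650 in zygotes as mean signals, AGO4A had 22960, 23840 and 23520, and the Polycomb gene fie had 14100, 13450 and 12540. Of the cell cycle list, EL2, an inhibitor of cell cycle kinases, had 12350, 29620 and 24680, and SMR1 had 16720, 7875 and 18900. Their lists did not pass the threshold in any contrast. EXPB9, an expansin, read 838.5 in zygote replicate 1 against 24140 and 28280 in the other zygote arrays.

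The lower signals after fertilization are open to a difference in amplification. With the ratio of poly-A to hybridization spikes as a covariate, 0 probe sets differed among stages, but the ratio parts the egg arrays from the others without overlap. Stage and amplification therefore cannot be told apart where these probe sets differ from egg cells. Whether the ratio reflects amplification or the amount of spike added was not tested. RAB21 had a similar estimate with a wider error (-5.81 ± 0.60 to -5.71 ± 2.42, SE) and lost its call (adjusted p = 0.898 by limma). Rf2 and OsPDIL2-3 went to -0.12 ± 1.25 and -0.39 ± 1.24. LOC4331855 had mean signals of 2864, 635.5 and 2233 in the order of the stages, while the ratio was alike in fertilized eggs and zygotes. Rf2 stayed low in zygotes (7396, 1621 and 1398), and LOC4343334 fell further (5450, 2610 and 974.1). These genes were picked after their values were seen. No probe set passed between fertilized eggs and zygotes, so the values do not decide. Without zygote replicate 2, which stood apart, 32 probe sets differed, so the count did not depend on including that array. Leaving out a noisy array also narrows the shared spread, so the higher count does not show how that array affected the called probe sets. In 5 of 100 splits of the arrays, the stages included, as many as 18 probe sets were called, so chance is not excluded. The highest other split gave 270, several times the real count, which points to a structure of the samples; what it is was not tested. With weights 4 of 100 splits reached 1569, and the highest other gave 3515.

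Pairs of stages have 10 splits, too few for a share under 0.05. Fertilized egg minus egg called 12 against 0 in the highest other split (1 of 10 splits as large), and 1247 against 1460 with weights (2 of 10). Zygote minus egg called 20 against 0 (1 of 10), and 561 against 223 with weights (1 of 10). Zygote minus fertilized egg called 0 against 6 (10 of 10), and 0 against 0 with weights (10 of 10).

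The rise of ribosomal proteins may be part of a rise of bright transcripts in general. Among 1000 lists of equally bright genes, the ribosomal median of 0.61 at about 1 hap lay at percentile 90.8, with a matched median of 0.41, and at about 3 hap the median of 0.47 lay at percentile 46.2, with a matched median of 0.48. After quantile normalization the adjusted p against eggs was 0.0854 at about 1 hap and 0.0123 at about 3 hap, and 0.442 at about 3 hap with weights added. The brightness test goes with a shift of bright transcripts at both times. Scaling is not excluded at about 1 hap, quantile normalization alone does not remove the call at about 3 hap, and a change of ribosomal proteins beyond the shift stays open.

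The defence genes higher in fertilized eggs may belong to a wider defence response, which was tested on a list written after these genes were seen. The other 21 members had a median log2 change of 0.34 against 0.01 for all genes, 13 of them above 0 (p = 0.722 by limma's camera, n = 21 genes, and 0.251 with weights), which leaves the hypothesis undecided. With weights 1 of them passed, PAL06 (log2 change 2.19 without weights; adjusted p = 0.0185 by limma with weights), and CYP99A2 did not (2.55; 0.0732). Of these members 8 were below 0, among them Chia1d at -4.93, which read 10060 in egg cell replicate 2 and 284.4 and 104.7 in the other egg arrays, Chib3H-h at -1.82, Chib3H-a at -1.51 and Cht10 at -1.39. Cells of the ovule wall in the fertilized egg samples are another candidate source, and the ovule wall and nucellus list gave p = 0.178 by limma's camera (n = 27 genes) with a median of -0.14, which does not decide either. Its median signal was highest in egg cell replicate 2, at 715. A response to pollination or to cell isolation was not tested. With the 3′ to 5′ ratio as a covariate and no weights, the 12 named rises had log2 changes from 1.50 (4CL5) to 4.59 (Cht4), with adjusted p from 0.152 to 0.72 by limma; Cht4 had 6.73 without it.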
